A study of Homo sapiens with 12 samples.

How the data were processed

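Total RNA from 12 cultures of HEK-293 cells (3 biological replicate transfections for each of 4 siRNAs, 40 nM, 72 h) was depleted of ribosomal RNA and sequenced as stranded paired-end libraries, per the labels' protocols. The deposited table lists 24040 genes by Ensembl ID. Its counts per library are raw whole numbers, per the file headers. The submitters' processing notes name fastp, HISAT2, featureCounts and limma and the builds hg19 and GRCh37, without versions or settings, and state neither the use of strand in counting nor a filter on low counts. Each listed gene had reads in at least 5 libraries. The deposited CPM values equal each count per M counts of its library with no further scaling, as tested on the values (largest difference 5e-04). Deposited log2 fold changes of each knockdown against siNS, with average log2 expression, come from the authors per the file headers. The authors' p-value and FDR for each gene are deposited beside them. A further log2 value called Confect in the deposited headers is not defined there and was not used.

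All tests here started from the deposited counts. Genes were kept by edgeR's filterByExpr (23869 of 24040), libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 12 libraries (edgeR 4.0.16, R 4.3.3; prior degrees of freedom 19.4, common biological coefficient of variation 0.0883). Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were each knockdown against siNS and the 3 pairs of knockdowns. Standard errors are the absolute log2 fold change over the square root of the F statistic, and CPM values in the text use TMM-scaled library sizes. Gene symbols came from a table of Ensembl IDs and names, which matched 22984 of the 24040 IDs. No genome annotation of the builds used was at hand, so no coordinates are given.

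Gene lists (31, written from general knowledge of the pathways) were tested with camera (limma 3.58.1) at its preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists within a comparison. Of the 186 list tests, 75 passed, and none of these 75 held with an estimated correlation. The lists cover the DZF family, double-stranded RNA and small RNA factors, interferon, NF-kB and antigen presentation genes, SR proteins, hnRNP proteins, the core spliceosome and other splicing regulators, and nonsense-mediated decay factors and substrates. They also cover ATF4, chaperone, p53, G1/S, G2/M, recombination, histone, ribosomal protein, ribosome biogenesis, cholesterol, hypoxia, oxidative phosphorylation, mitochondrial mRNA, nuclear noncoding RNA and immediate early genes, and neuronal, blood, fibroblast, epithelial and endothelial markers. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined, apart from what is named as added later.

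Genes were named by rule. ZFR, ZFR2, ILF2, ILF3 and STRBP are given throughout and MACROH2A1 against siNS, and IFNB1 is not in the table. For each knockdown against siNS the 10 largest rises and falls are named, and for each pair of knockdowns the 5 largest, among called genes with a symbol, a mean of at least 5 CPM and no overlap between the libraries of both groups. In each list described, members are named in order of p, at most 4. For the overlap, the 5 genes raised and the 5 lowered in all 3 knockdowns with the largest smallest change are named. MYC, CDKN1A, RPA2 and SMG5 were named outside their rule in some comparisons after their values were seen.

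Sites in 3′ UTRs were searched in GENCODE release 29 transcripts, for 15090 tested genes with at least 50 annotated bases. All 16384 heptamers were ranked in a random part of the 10567 such genes with a mean of at least 5 CPM, with log2 fold changes limited to 1.5 either way, by a linear model with terms for UTR length, GC content and mean expression, in which the score of a heptamer was combined with that of its partner shifted by 1 base and ending in A. The best was tested in the remaining genes with 10000 permutations. Tested on simulated data, the gene test recovered 73 of 100 genes changed 1.5-fold and 92 of 100 changed 2-fold for siZFR against siNS, with 10 false calls among 23869 genes. The same counts were 76, 93 and 9 for siILF2 against siNS, 76, 88 and 8 for siILF3 against siNS, 78, 87 and 10 for siILF2 against siILF3, 82, 93 and 13 for siZFR against siILF2, and 72, 93 and 7 for siZFR against siILF3. A shift of 0.3 planted in the ribosome biogenesis list was found with 0 other lists called. In these simulations each gene was drawn independently. Correlation between genes is thus absent, and the list result does not test camera's preset correlation. The heptamer search found a planted shift of 0.25 in 10 of 10 simulations and of −0.1 in 9 of 10.

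Depth was 114.01 to 137.8 M counts per library. Alternatives were DESeq2 size factors, no filter on low counts, a mean of at least 5 CPM, the DESeq2 Wald test (1.42.0), limma-voom, a fit of the 6 libraries compared, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and fry. Recounts without genes that carry the siNS heptamer, splits of the siNS libraries between knockdowns, a recount of decay substrates without the 3 members shared with the ATF4 list, and tests of 2 further lists against matched genes were added after the data were seen. All 12 libraries were used. Genes removed by the filter, 1 deposited column of zeros and the Confect values were not.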

Results

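The data are RNA sequencing counts per gene from HEK-293 cells, an established human embryonic kidney line, harvested 72 h after transfection with 40 nM of an siRNA. Each of 4 groups held 3 libraries, which received a non-silencing siRNA (siNS) or an siRNA against ZFR, ILF2 or ILF3 (siZFR, siILF2 and siILF3). The proteins of these genes share a DZF domain, through which members of the family pair, and the series asks how they act together in alternative splicing. Counts per gene do not measure exon usage, so every comparison here concerns the RNA level of whole genes. The siNS libraries held 119.6, 120.2 and 119.6 M counts. Totals were 130.5, 131.5 and 131.5 M in siZFR, 114.01, 121.1 and 126.4 M in siILF2, and 137.8, 123.4 and 129.2 M in siILF3.

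Mitochondrial ribosomal RNA took 32.3% of the counts of siNS replicate 3 and 23.2% and 22.1% of those of siNS replicates 1 and 2. Its share was 21.2% to 27.2% in siZFR, 27.3% to 31.5% in siILF2 and 23% to 28.3% in siILF3. Counts of changed genes against siNS are also given without siNS replicate 3. Other groups held pairs as unlike. Across genes, log2 CPM correlated at r = 0.9925 between siNS replicate 3 and either other siNS library. Between siZFR replicates 1 and 2 it correlated at 0.9914, the lowest value within any group. The deposited table of the authors calls 6360, 6591 and 7446 genes at an FDR under 0.05 in siZFR, siILF2 and siILF3 against siNS. Of these, 6119, 6427 and 7239 were also called here, and across genes, which are not independent replicates, the log2 fold changes of both sources correlated at r = 0.979, 0.979 and 0.979. Use of strand in the counting is not stated, so reads of overlapping and antisense genes cannot be separated.

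Each targeted RNA fell in every library of its own knockdown. ZFR (ENSG00000056097) lay at 36.7, 35.6 and 38.3 CPM (counts scaled by library size) in the siZFR libraries and at 159, 153.9 and 142.1 CPM in the siNS libraries, a 4.11-fold fall (log2 fold change −2.04, SE 0.0695, adjusted p = 3.78e-18). ILF2 (ENSG00000143621) lay at 72.9, 74.6 and 71.4 CPM in siILF2 and at 327, 326.5 and 299.5 CPM in siNS, a 4.36-fold fall (−2.12, SE 0.0777, adjusted p = 4.23e-17). ILF3 (ENSG00000129351) was at 136.9, 131.8 and 127.7 CPM in siILF3 against 262.7, 270.2 and 266.3 CPM in siNS, a 2.02-fold fall (−1.01, SE 0.0681, adjusted p = 5.58e-12).

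The partner genes moved as well. ZFR rose to 372.6 ± 5.29 CPM (SD, n = 3) in siILF2 (1.30) and to 244.6 ± 6.46 CPM in siILF3 (0.69). ILF3 rose to 418.8 ± 7.39 CPM in siILF2 (0.65) and did not pass the test in siZFR (0.14, adjusted p = 0.144). In siZFR, ILF2 fell to 265.4 ± 27.1 CPM (−0.26, adjusted p = 0.01), a call lost without siZFR replicate 2 (adjusted p = 0.0599) and in a fit of the 6 libraries compared (adjusted p = 0.0656). In siILF3, ILF2 stayed near its control level (−0.01, adjusted p = 0.968). STRBP rose in siILF2 (0.25, adjusted p = 0.00673) and in siILF3 (0.29, adjusted p = 0.00188) and did not pass in siZFR (0.06, adjusted p = 0.609). ZFR2 was called in no comparison, at 0.0788 to 0.17 CPM. ZFR, ILF3, STRBP and ZFR2 carry GCAGTAC or CAGTACA in their 3′ UTR. Either of the pair is called the siNS heptamer here and is described with the overlap of the knockdowns.

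**Figure D1:**
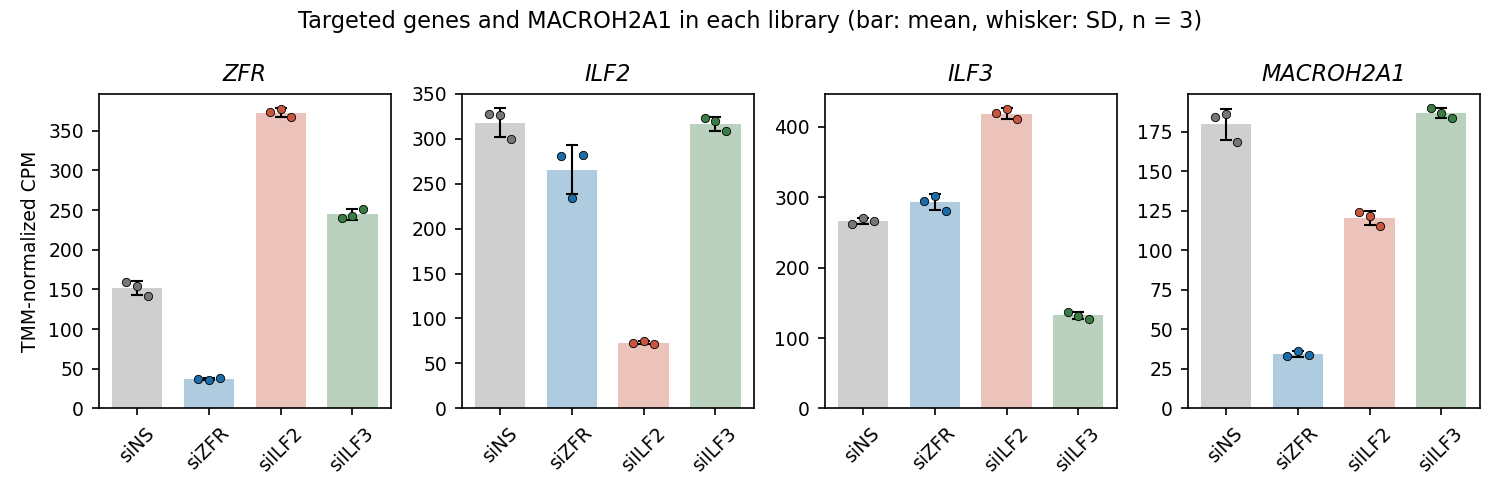
RNA levels of ZFR, ILF2, ILF3 and MACROH2A1 in CPM (vertical axis from 0) in the 4 groups, with 1 point per library, a bar at the mean and a whisker of 1 SD (n = 3). Each targeted gene is lowest in its own knockdown, and MACROH2A1 lies at 34.4 ± 1.71 CPM in siZFR against 179.6 ± 9.68 CPM in siNS.

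The comparison of siZFR with siNS asks which RNAs depend on ZFR. Knockdown of ZFR lowered MACROH2A1, which encodes a variant histone, further than ZFR itself. Lists of amino acid supply genes under the transcription factor ATF4, of transcripts removed by nonsense-mediated decay and of ribosomal protein genes fell, while p53 targets and replication-dependent histone genes rose, and with an estimated correlation no called list held (adjusted p from 0.352 to 0.933). The p53 call was also lost without genes that carry the siNS heptamer (adjusted p = 0.196). Of 23869 genes tested, 6306 changed by edgeR's quasi-likelihood test, of which 3100 rose and 3206 fell. At least 2-fold changes numbered 299 up and 314 down, and without siNS replicate 3 the count of changed genes was 5968.

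MACROH2A1 (ENSG00000113648) fell from 179.6 ± 9.68 to 34.4 ± 1.71 CPM (log2 fold change −2.38, SE 0.0677, adjusted p = 5.91e-20). After MACROH2A1 and ZFR, the largest falls were those of the executioner caspase gene CASP7 (−1.44, SE 0.0624, adjusted p = 5.01e-16), the importin gene KPNA6 (−1.44, SE 0.0724, adjusted p = 1.11e-14), the collagen galactosyltransferase gene COLGALT2 (−1.42, SE 0.0707, adjusted p = 9.33e-15) and ANXA1 (−1.34), CREBL2 (−1.32), LUM (−1.25), SNHG32 (−1.17) and RHOB (−1.16), where bracketed values are log2 fold changes. The semaphorin gene SEMA6B rose from 3.32 ± 0.0282 to 11.5 ± 1.43 CPM (1.79, SE 0.101, adjusted p = 1.1e-13) and talin gene TLN1 from 46.9 ± 4.03 to 161.9 ± 13.2 CPM (1.79, SE 0.0734, adjusted p = 2.1e-16). The next largest rises were EMP2 (1.76), TMEM170B (1.76), NID1 (1.74), APOE (1.67), ALCAM (1.64), IL10RB (1.55), ZCCHC12 (1.55) and FN1 (1.54). Of these 10 rises, 7 carry the siNS heptamer, and SEMA6B, APOE and ZCCHC12 do not.

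ATF4 activates genes of amino acid synthesis and uptake under stress. Of the 26 genes of the ATF4 and integrated stress response list, 20 fell, 1 rose and 5 did not pass (21 and 1 adjusted over the list alone), and camera's adjusted p = 2.51e-12, or 0.572 with an estimated correlation. The members with the smallest p were ATF4 (−1.04), SLC7A11 (−1.01) and ASNS (−0.72). Nonsense-mediated decay removes transcripts with early stop codons, among them hosts of small nucleolar RNAs. Among 16 nonsense-mediated decay substrates, 12 fell, 0 rose and 4 did not pass (14 and 0 adjusted over the list alone), with adjusted p = 1.02e-12, or 0.352 with an estimated correlation, and the leading members were GAS5 (−1.08), ZFAS1 (−0.92) and ATF4 (−1.04). The list shares ATF4, PPP1R15A and SLC7A11 with the ATF4 list, and without these 3 members, a recount added after the data were seen, 9 of 13 fell and 0 rose (adjusted p = 4.34e-09). Decay factors moved as single genes, as in SMG5 (−0.79) and CASC3 (0.41), while 4 rose, 2 fell and 11 did not pass (6 and 5 adjusted over the list alone) and the list did not pass (adjusted p = 0.935, or 0.988 with an estimated correlation). Of 79 cytosolic ribosomal protein genes 38 fell, 0 rose and 41 did not pass (48 and 0 adjusted over the list alone), led by RPL17 (−0.67), RPL12 (−0.64) and RPS10 (−0.54) (adjusted p = 1.51e-11, or 0.907 with an estimated correlation). Ribosomal protein genes have many processed pseudogenes and histone genes have near-identical copies, so how the counting split their reads is uncertain in every comparison. In the ribosome biogenesis list, 14 fell, 1 rose and 23 did not pass (15 and 1 adjusted over the list alone), with adjusted p = 0.00312, or 0.907 with an estimated correlation, and POLR1A (0.52) and NOP14 (−0.50) had the smallest p. For nuclear-encoded oxidative phosphorylation, 6 fell, 0 rose and 29 did not pass (6 and 0 adjusted over the list alone), with UQCRFS1 (−0.35) and NDUFV2 (−0.56) in front (adjusted p = 0.00354, or 0.933 with an estimated correlation). Without siZFR replicate 2 the adjusted p of this last list was 0.177, and with fry it was 0.148.

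Targets of the tumour suppressor p53 rose as a list: 12 rose, 3 fell and 10 did not pass (14 and 3 adjusted over the list alone), with adjusted p = 0.00312, or 0.907 with an estimated correlation. Members with the smallest p were TP53INP1 (0.74), MDM2 (0.46) and RRM2B (0.38), whereas CDKN1A (0.01) did not change (adjusted p = 0.961). The siNS heptamer is carried by 7 of these 25 genes, and without genes that carry it camera's adjusted p was 0.196. Replication-dependent histone genes also rose, in that 8 rose, 1 fell and 7 did not pass (10 and 1 adjusted over the list alone) (adjusted p = 0.00216, or 0.907 with an estimated correlation). The list did not pass with fry (adjusted p = 0.0757). H1-3 (0.58) rose and H1-4 (−0.59) fell. Lists of splicing proteins did not pass: SR proteins had 4 falls, 2 rises and 7 not passed (7 and 2 adjusted over the list alone), with adjusted p = 0.206, or 0.907 with an estimated correlation. For hnRNP proteins the list had 9 rises, 7 falls and 11 not passed (9 and 7 adjusted over the list alone), with adjusted p = 0.935, or 0.988 with an estimated correlation. The core spliceosome list, in which 9 fell, 2 rose and 39 did not pass (9 and 2 adjusted over the list alone), had adjusted p = 0.0717, or 0.988 with an estimated correlation, and passed without siNS replicate 3 (adjusted p = 0.00399), siZFR replicate 1 (0.00874), siZFR replicate 3 (0.0379) or genes that carry the siNS heptamer (0.0389). Single splicing genes that changed included SRSF6 (0.46) and SRSF5 (−0.41), PTBP3 (0.78) and HNRNPDL (−0.58) and QKI (0.92) and MBNL3 (0.43). The 4 of these that rose, SRSF6, PTBP3, QKI and MBNL3, carry the siNS heptamer. The list of other splicing regulators had 8 falls, 6 rises and 20 not passed (10 and 6 adjusted over the list alone) (adjusted p = 0.935, or 0.988 with an estimated correlation). Interferon-stimulated genes, relevant to proteins that bind double-stranded RNA, did not pass as a list: 7 fell, 5 rose and 27 did not pass (8 and 6 adjusted over the list alone) (adjusted p = 0.795, or 0.988 with an estimated correlation), with falls of IFI44L (−0.83), MX1 (−0.93) and IFI35 (−0.61).

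The comparison of siILF2 with siNS asks which RNAs depend on ILF2. Lists of replication-dependent histones and G1/S replication genes rose after ILF2 knockdown, and ATF4 targets, endoplasmic reticulum chaperones, p53 targets, antigen presentation genes and nonsense-mediated decay substrates fell. All list calls in siILF2 were lost with an estimated correlation (adjusted p from 0.459 to 0.463). MACROH2A1 fell here too, by less than in siZFR. The test called 6716 of 23869 genes, with 3134 raised and 3582 lowered, and 6817 without siNS replicate 3. Changes of at least 2-fold numbered 260 up and 441 down.

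After ILF2, the largest fall was that of annexin gene ANXA1, from 21.6 ± 0.226 to 6.43 ± 0.47 CPM (log2 fold change −1.75, SE 0.0884, adjusted p = 1.98e-14). The p53 target SPATA18 fell from 11.6 ± 0.838 to 3.89 ± 0.232 CPM (−1.58, SE 0.089, adjusted p = 1.58e-13) and the smooth muscle actin gene ACTA2 from 22.0 ± 2.08 to 7.49 ± 0.733 CPM (−1.56, SE 0.0927, adjusted p = 4.71e-13). Other large falls were those of RWDD2B (−1.51), BEX1 (−1.45), TCTA (−1.44), APH1B (−1.38), GLIPR2 (−1.36) and ALDH4A1 (−1.34). MACROH2A1 fell to 120.4 ± 4.6 CPM (−0.58). The largest rises were EMP2 (1.75), ALCAM (1.74), TLN1 (1.63), SCAMP1 (1.53), NUDT15 (1.52), TMEM170B (1.49), ELAVL2 (1.45), PXYLP1 (1.44) and DISC1 (1.37) and that of linker histone gene H1-3, from 65.6 ± 1.82 to 167.7 ± 11.8 CPM (1.36, SE 0.075, adjusted p = 1.04e-13). All 9 of these rises with an annotated 3′ UTR that could be searched carry the siNS heptamer, and H1-3 was not searched.

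Replication-dependent histones, made in S phase, rose widely: 14 rose, 0 fell and 2 did not pass (15 and 0 adjusted over the list alone) (adjusted p = 4.69e-11, or 0.459 with an estimated correlation). After H1-3 the leading members were H4C3 (0.75), H2AC20 (0.70) and H2BC4 (0.66). Among 31 G1/S replication genes, 22 rose, 3 fell and 6 did not pass (22 and 3 adjusted over the list alone), with adjusted p = 3.47e-06, or 0.463 with an estimated correlation. Members that rose included MCM2 (0.60) and MCM3 (0.53), while RPA2 (−1.28) and CDC25A (−0.67) fell. ATF4 and integrated stress response genes fell, since 21 fell, 2 rose and 3 did not pass (21 and 2 adjusted over the list alone) (adjusted p = 4.69e-11, or 0.459 with an estimated correlation), led by MTHFD2 (−1.03), SLC7A5 (−0.88) and ASNS (−0.69). Endoplasmic reticulum chaperones help secreted proteins fold, and of 20 genes 13 fell, 1 rose and 6 did not pass (14 and 1 adjusted over the list alone), with adjusted p = 1.24e-05, or 0.459 with an estimated correlation and XBP1 (−0.70), EDEM1 (−0.67) and CALR (−0.52) in front. For p53 targets, 13 fell, 2 rose and 10 did not pass (15 and 2 adjusted over the list alone), with adjusted p = 1.24e-05, or 0.459 with an estimated correlation, and after SPATA18 the members with the smallest p were CDKN1A (−0.94), TP53I3 (−0.997) and XPC (−0.63).

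Nonsense-mediated decay substrates fell, as 9 fell, 0 rose and 7 did not pass (9 and 0 adjusted over the list alone) (adjusted p = 2e-04, or 0.463 with an estimated correlation), with PPP1R15A (−0.68), ATF4 (−0.65) and SLC7A11 (−0.60), and the decay factor gene SMG5 fell by 0.62 on the log2 scale. These 3 leading substrates are also members of the ATF4 list, and without them 6 of 13 fell and 0 rose (adjusted p = 0.0179). In the nonsense-mediated decay factor list, 7 fell, 4 rose and 6 did not pass (7 and 5 adjusted over the list alone), with adjusted p = 0.896, or 0.951 with an estimated correlation. Antigen presentation genes, which display peptides to T cells, had 8 falls, 2 rises and 5 not passed (8 and 2 adjusted over the list alone), with adjusted p = 0.00204, or 0.459 with an estimated correlation, led by HLA-B (−0.68), HLA-E (−0.62) and TAPBP (−0.60). Hypoxia and glycolysis genes rose (6 rose, 0 fell and 12 did not pass (6 and 0 adjusted over the list alone), adjusted p = 0.00564, or 0.463 with an estimated correlation), with BNIP3 (0.51), PDK1 (0.42) and EGLN3 (0.40) in front. Among neuronal markers 6 fell, 0 rose and 8 did not pass (6 and 0 adjusted over the list alone) (adjusted p = 0.0324, or 0.459 with an estimated correlation), with falls of GAP43 (−1.31), SYP (−0.86) and INA (−0.46). Proteins of the hnRNP family bind nascent RNA, and of their 27 genes 7 rose, 2 fell and 18 did not pass (9 and 2 adjusted over the list alone), with adjusted p = 0.0189, or 0.463 with an estimated correlation. This hnRNP call, led by PTBP3 (0.76), HNRNPUL1 (0.76) and HNRNPD (0.57), was lost without siNS replicate 3 (adjusted p = 0.065). SR proteins (5 rose, 0 fell and 8 did not pass (7 and 1 adjusted over the list alone), adjusted p = 0.0756, or 0.463 with an estimated correlation), the core spliceosome (8 rose, 6 fell and 36 did not pass (8 and 6 adjusted over the list alone), adjusted p = 0.758, or 0.951 with an estimated correlation) and other splicing regulators (8 rose, 3 fell and 23 did not pass (8 and 3 adjusted over the list alone), adjusted p = 0.0747, or 0.463 with an estimated correlation) did not pass. Without siNS replicate 3, SR proteins (adjusted p = 0.035) and other splicing regulators (adjusted p = 0.0418) passed, the latter also without siILF2 replicate 2 (0.0498) or 3 (0.0364). Interferon-stimulated genes moved both ways (9 fell, 8 rose and 22 did not pass (9 and 8 adjusted over the list alone), adjusted p = 0.956, or 0.979 with an estimated correlation), as OAS3 (−0.80), IFIT1 (0.70) and SAMD9 (0.62) show.

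The comparison of siILF3 with siNS asks which RNAs depend on ILF3, the partner of ILF2. Lists of replication-dependent histones, mitosis genes, ribosomal proteins, ribosome biogenesis, hnRNP proteins and the core spliceosome rose, and p53 targets, endoplasmic reticulum chaperones, interferon-stimulated genes and neuronal and mesenchymal markers fell. None of the lists called in siILF3 held with an estimated correlation (adjusted p from 0.194 to 0.495). MACROH2A1 did not pass, at 186.7 against 179.6 CPM in siNS (0.06, adjusted p = 0.559). MYC, which encodes a transcription factor of growth and ribosome genes, rose from 47.1 ± 3.33 to 119.1 ± 3.3 CPM (1.34, SE 0.0703, adjusted p = 3.59e-14). The test called 7499 of 23869 genes, with 3753 up and 3746 down, and 7046 without siNS replicate 3. Falls of at least 2-fold (818) outnumbered such rises (160). Changes of any size went the other way among genes with a mean of at least 5 CPM and a searched 3′ UTR. Of the 1409 with the siNS heptamer 537 rose and 192 fell, and of the 9158 without it 2514 rose and 1444 fell.

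Phosphatase gene INPP5D fell from 10.0 ± 0.796 to 2.26 ± 0.329 CPM (log2 fold change −2.15, SE 0.107, adjusted p = 1.35e-14) and ANXA1 to 6.37 ± 0.571 CPM (−1.76, SE 0.0882, adjusted p = 1.35e-14). Further large falls were TP53I3 (−1.56), SPATA18 (−1.55), LOXL4 (−1.52), LUM (−1.50), SSPOP (−1.46), SHISA2 (−1.42) and KATNAL2 (−1.41) and the cell cycle inhibitor CDKN1A (−1.38), from 147.9 ± 11 to 56.8 ± 3.11 CPM. The gene listed as MIR3648-2 showed the largest rise (2.04, SE 0.162, adjusted p = 1.62e-10). It lies in ribosomal RNA precursor sequence, so the source of its reads is uncertain. Mitochondrial topoisomerase gene TOP1MT rose from 4.43 ± 0.328 to 16.1 ± 0.681 CPM (1.86, SE 0.0831, adjusted p = 1.79e-15) and the argonaute gene AGO4 from 26.7 ± 1.44 to 79.6 ± 3.69 CPM (1.58, SE 0.0645, adjusted p = 7.39e-16). Other large rises were EMP2 (1.77), TLN1 (1.74), STEAP3 (1.55), PXYLP1 (1.55), ALCAM (1.49), NID1 (1.48) and NUDT15 (1.41). All 9 of the 10 largest rises that could be searched carry the siNS heptamer, while MIR3648-2 was not searched.

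Histone genes rose most widely: 15 rose, 0 fell and 1 did not pass (15 and 0 adjusted over the list alone) (adjusted p = 5.79e-12, or 0.272 with an estimated correlation), led by H4C3 (0.94), H2AC20 (0.78) and H2BC4 (0.70). Among 32 G2/M mitosis genes, 21 rose, 0 fell and 11 did not pass (21 and 0 adjusted over the list alone), with adjusted p = 5.02e-10, or 0.415 with an estimated correlation and PLK1 (0.79), KIF20A (0.73) and KIF11 (0.66) in front. G1/S replication genes had 14 rises, 1 fall and 16 not passed (16 and 1 adjusted over the list alone), with adjusted p = 2.76e-06, or 0.415 with an estimated correlation and rises of E2F2 (0.58), MCM2 (0.59) and UNG (0.41). Of 79 ribosomal protein genes 51 rose, 1 fell and 27 did not pass (61 and 1 adjusted over the list alone) (adjusted p = 2.35e-11, or 0.415 with an estimated correlation), with RPS29 (0.45), RPS23 (0.39) and RPS15 (0.40) in front. In the ribosome biogenesis list 23 rose, 0 fell and 15 did not pass (27 and 0 adjusted over the list alone), with adjusted p = 6.32e-09, or 0.401 with an estimated correlation and rises of POLR1A (0.56), WDR3 (0.55) and FBL (0.51). Nuclear-encoded oxidative phosphorylation genes rose, since 16 rose, 1 fell and 18 did not pass (17 and 2 adjusted over the list alone) (adjusted p = 0.00126, or 0.495 with an estimated correlation), led by SDHB (0.37), CYC1 (0.37) and COX4I1 (0.29). Genes with a mean of at least 5 CPM and no siNS heptamer also leaned up in siILF3: 27.5% rose and 15.8% fell, with a median of 0.0565. The median of all tested genes was −0.017. Ribosomal, oxidative phosphorylation, hnRNP and spliceosome lists were not set against matched genes in this comparison, so part of their rise may be shared with other well-expressed genes. Hypoxia and glycolysis genes rose as well (9 rose, 1 fell and 8 did not pass (10 and 1 adjusted over the list alone), adjusted p = 0.00334, or 0.415 with an estimated correlation), with NDRG1 (0.79), BNIP3 (0.53) and LDHA (0.45).

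Among the splicing lists, hnRNP proteins and the core spliceosome rose. For hnRNP proteins, 15 rose, 0 fell and 12 did not pass (18 and 0 adjusted over the list alone), with adjusted p = 8.03e-06, or 0.272 with an estimated correlation and PTBP3 (0.81), HNRNPUL1 (0.52) and HNRNPD (0.61) in front. The core spliceosome had 22 rises, 2 falls and 26 not passed (25 and 2 adjusted over the list alone), with adjusted p = 1.76e-05, or 0.415 with an estimated correlation, led by USP39 (0.52), SNRPA (0.48) and U2AF2 (0.44). SR proteins (3 rose, 0 fell and 10 did not pass (3 and 0 adjusted over the list alone), adjusted p = 0.0677, or 0.415 with an estimated correlation) passed only without siNS replicate 3 or siILF3 replicate 2 among the libraries left out in turn (adjusted p = 0.0222 and 0.0495). Other splicing regulators, with QKI (0.81) and SRPK1 (0.46), did not pass (9 rose, 2 fell and 23 did not pass (9 and 2 adjusted over the list alone), adjusted p = 0.117, or 0.415 with an estimated correlation). Genes of double-stranded RNA binding and small RNA processing had 5 rises, 1 fall and 10 not passed (5 and 1 adjusted over the list alone), with adjusted p = 0.019, or 0.415 with an estimated correlation, and TNRC6A (0.74), AGO2 (0.76) and DHX9 (0.40) rose. That call was lost without siNS replicate 3 (adjusted p = 0.0601) and without genes that carry the siNS heptamer (adjusted p = 0.115). Nonsense-mediated decay substrates fell (7 fell, 2 rose and 7 did not pass (8 and 2 adjusted over the list alone), adjusted p = 0.0255, or 0.468 with an estimated correlation), as in PPP1R15A (−0.67), GADD45A (−0.53) and ZFAS1 (−0.54), a call lost without siNS replicate 3 (adjusted p = 0.101), without siILF3 replicate 3 (adjusted p = 0.0757) or without the 3 members shared with the ATF4 list (adjusted p = 0.239, with 4 of 13 lower and 2 higher). The factors of this pathway did not pass (7 rose, 4 fell and 6 did not pass (8 and 4 adjusted over the list alone), adjusted p = 0.193, or 0.522 with an estimated correlation), although CASC3 (0.61) and RNPS1 (0.70) rose.

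Targets of p53 fell: 16 fell, 1 rose and 8 did not pass (17 and 2 adjusted over the list alone), with adjusted p = 5.89e-08, or 0.272 with an estimated correlation and the smallest p for CDKN1A (−1.38), SPATA18 (−1.55) and TP53I3 (−1.56). Endoplasmic reticulum chaperones had 8 falls, 1 rise and 11 not passed (8 and 1 adjusted over the list alone) (adjusted p = 0.00509, or 0.415 with an estimated correlation), with falls of DNAJB9 (−0.92), XBP1 (−0.59) and EDEM1 (−0.44). Interferon-stimulated genes had 17 falls, 7 rises and 15 not passed (19 and 7 adjusted over the list alone), with adjusted p = 0.017, or 0.415 with an estimated correlation, and OAS3 (−1.03) and PARP14 (−0.59) fell while IFIT1 (0.78) and TRIM25 (0.57) rose. Neuronal markers fell (9 fell, 0 rose and 5 did not pass (9 and 0 adjusted over the list alone), adjusted p = 0.00122, or 0.194 with an estimated correlation), among them MAP2 (−1.15), SYT1 (−0.56) and NCAM1 (−0.30), as did fibroblast and mesenchymal markers (6 fell, 1 rose and 5 did not pass (6 and 1 adjusted over the list alone), adjusted p = 0.0158, or 0.415 with an estimated correlation), with ACTA2 (−1.32), LUM (−1.50) and VIM (−0.54). ATF4 and integrated stress response genes had 10 falls, 1 rise and 15 not passed (11 and 1 adjusted over the list alone), with adjusted p = 0.0505, or 0.623 with an estimated correlation, and passed without siNS replicate 3 (adjusted p = 0.00562), siILF3 replicate 1 (0.0106) or siILF3 replicate 2 (0.0254).

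**Figure D2:**
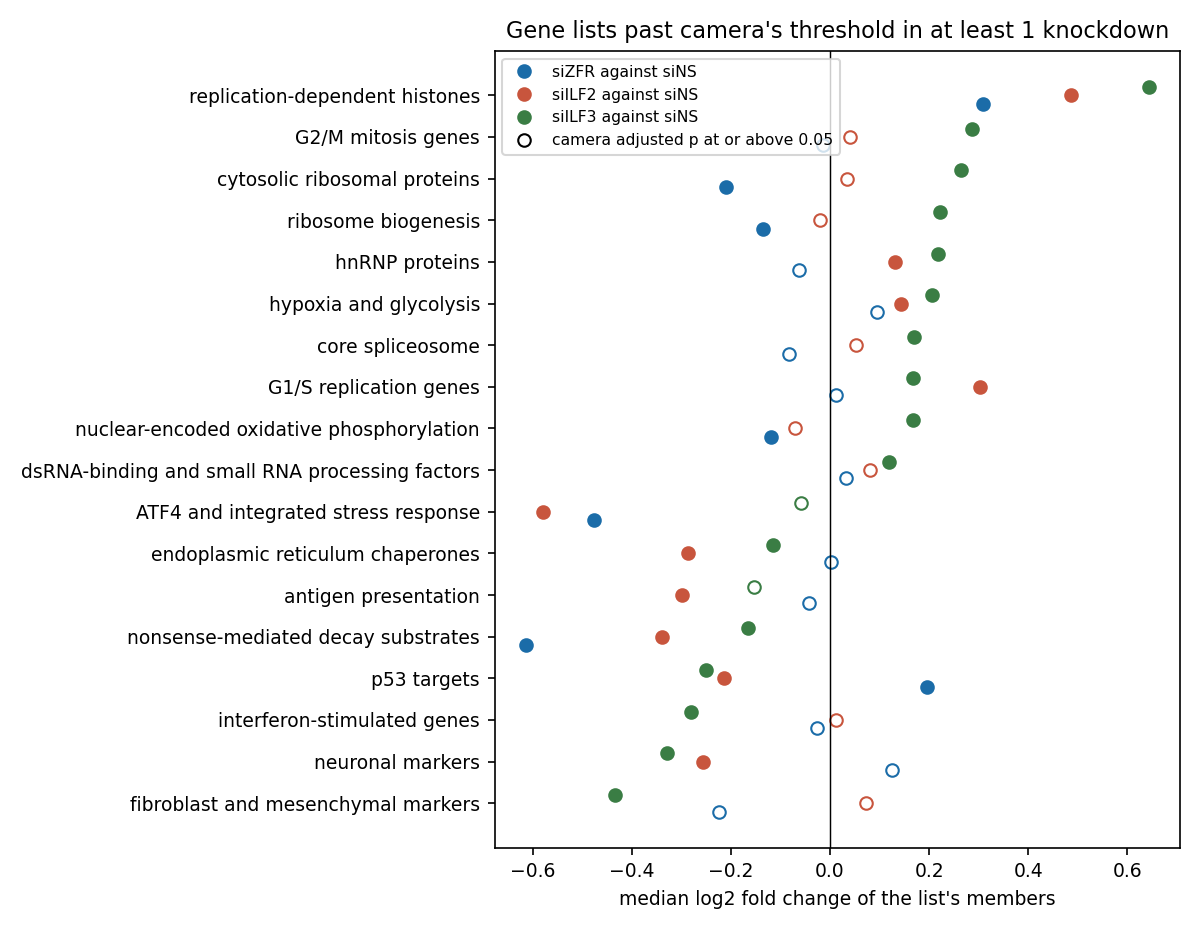
Median log2 fold change against siNS (horizontal axis) of the gene lists that passed camera's test in at least 1 knockdown, for siZFR, siILF2 and siILF3, with filled symbols for an adjusted p under 0.05. Ribosomal proteins have a median of −0.21 in siZFR and 0.27 in siILF3, and p53 targets of 0.20 in siZFR, −0.21 in siILF2 and −0.25 in siILF3.

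Set side by side, the 3 knockdowns shared many changed genes. In siILF2 and siILF3, 1726 genes rose in both and 1829 fell in both, while 264 moved in opposite directions. Independent lists of these sizes would share 492.8 and 562.2. For siZFR and siILF2 the counts were 1361 raised, 1342 lowered and 427 opposite (407 and 481.1 for independent lists), and for siZFR and siILF3 they were 1294, 1204 and 632 (487.4 and 503.1). In all 3 knockdowns 932 genes rose and 808 fell, against 64 and 75.5 for independent lists. Counts of all 12 libraries, siNS included, were also simulated with no group changed, in 20 simulations. Simulated groups shared a mean of 0.25, 0.15 and 0.1 calls for siZFR and siILF2, siZFR and siILF3, and siILF2 and siILF3. Each gene was drawn independently, so a departure of 1 siNS library across many genes at once is not in the simulation. The siNS libraries were also split, a test added after the data were seen, so that none served both knockdowns of a pair (1 and 2 libraries, 6 splits each). Medians of 708.5, 727 and 978 genes then rose in both (184.4, 207.6 and 227.4 expected for independent lists) and 711, 630.5 and 1106 fell in both (245.6, 226.8 and 307.8). With 1 siNS library per knockdown, medians of 436.5 and 285 genes rose and fell in all 3 (15.96 and 19.4 expected). Fewer control libraries enter each of these tests, and a response shared by all siNS libraries is not removed. Across genes, which are not independent replicates, log2 fold changes correlated at r = 0.419 for siZFR and siILF2 (Spearman's rho 0.389), 0.375 for siZFR and siILF3 (0.334) and 0.592 for siILF2 and siILF3 (0.542), where simulated unchanged groups gave 0.507, 0.51 and 0.499. Covariances were 0.0923, 0.0875 and 0.144, or 0.0529, 0.0483 and 0.105 above the simulated 0.0394, 0.0392 and 0.039. With split controls the median correlations were 0.1695, 0.131 and 0.2955, and the median covariances 0.05075, 0.0409 and 0.09635.

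Genes with the largest rise in all 3 knockdowns were EMP2, TLN1, ALCAM, NUDT15 and NID1. Their smallest log2 fold change in any knockdown was 1.30, that of NID1 in siILF2. The largest shared falls were ANXA1, LUM, MYO3A, SFXN2 and DNAH17, for which DNAH17 in siZFR had the smallest change (−0.79). All 5 shared rises and none of the 5 shared falls carry in an annotated 3′ UTR the heptamer GCAGTAC or CAGTACA. GCAGTAC was picked by its rise against siNS in these same data, so its excess among raised genes follows in part from that choice. Picked in a random part of the genes, it raised the mean change against siNS by 0.2631 (SE 0.0144) in the others. The shares and slopes below use all genes. Of 854 genes raised in all 3 knockdowns with a 3′ UTR to search, 317 (37.1%) carry GCAGTAC or CAGTACA, and of the 30 raised at least 2-fold in all 3, 25 (83.3%). The share was 6.02% (40 of 665) among genes lowered in all 3 and 11.6% (1757 of 15090) among all searched genes. With a mean of at least 5 CPM, 1409 of 10567 genes (13.3%) carry the site. Of those 1409, 38.2%, 39% and 38.1% rose in siZFR, siILF2 and siILF3 against siNS, compared with 17.8%, 18.7% and 27.5% of the 9158 without it. In the 3 comparisons between knockdowns, the median log2 difference of genes with and without the site was 0.00357 and −0.0609 for siILF2 against siILF3, 0.0058 and −0.00944 for siZFR against siILF2 and 0.00811 and −0.0708 for siZFR against siILF3. Against siNS it was 0.115 and −0.0188 in siZFR, 0.116 and −0.00542 in siILF2 and 0.101 and 0.0565 in siILF3. Those medians include genes with CAGTACA alone and are not adjusted. With terms for UTR length, GC content and expression, the slope for GCAGTAC was 0.2475 (SE 0.0113) in siZFR, 0.2608 (SE 0.0124) in siILF2 and 0.2492 (SE 0.0116) in siILF3 against siNS. For siILF2 against siILF3 it was 0.0106 (SE 0.0102), for siZFR against siILF2 −0.0101 (SE 0.0122) and for siZFR against siILF3 −0.000211 (SE 0.0121). With these terms taken out, genes with CAGTACA and not GCAGTAC stood at a mean of 0.0112 (SE 0.0108, 420 genes) against siNS in the part of the genes used for testing. Genes there without the hexamer CAGTAC in the 3′ UTR stood at −0.0195 (SE 0.00349, 4001 genes).

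**Figure D3:**
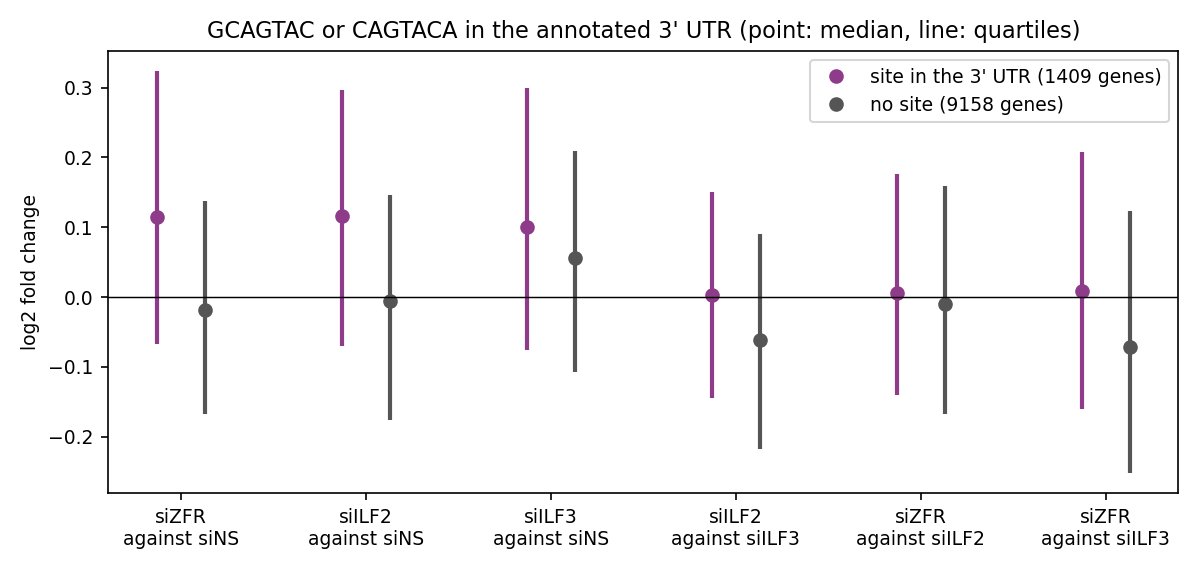
Log2 fold change (vertical axis; points, medians; bars, quartiles) of the 1409 genes with and the 9158 genes without GCAGTAC or CAGTACA in an annotated 3′ UTR, in 6 comparisons. Medians with and without the site are 0.12 and −0.02 in siZFR, 0.12 and −0.01 in siILF2 and 0.10 and 0.06 in siILF3 against siNS.

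The comparison of siILF2 with siILF3 asks whether loss of either partner of the ILF2 and ILF3 pair has the same effect. The siNS libraries enter it only through the shared scaling, filter and dispersion. Depth of knockdown was unequal: against siNS, ILF2 RNA fell 4.36-fold in siILF2 and ILF3 RNA 2.02-fold in siILF3. Counts do not measure protein. Differences between these groups may thus reflect depth as well as the gene targeted, which was not tested. Lists lower in siILF2 were ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, mitosis genes, core spliceosome and ATF4 targets, and lists higher were interferon-stimulated genes and nuclear-retained long noncoding RNAs. With an estimated correlation the 11 list calls were lost, at adjusted p = 0.551, or 0.595 for ribosomal proteins. Of 23869 genes, 6027 differed, with 2703 higher and 3324 lower in siILF2, and 401 and 104 of them at least 2-fold. Besides ILF3 (1.66) and ILF2 (−2.12), the largest differences were higher levels of DLEU2 (1.45), LINC01963 (1.27), H1-0 (1.13) and H1-3 (1.08) and lower levels of NDUFA13 (−1.74), CTSB (−1.61), PYCR1 (−1.52) and PLS3 (−1.44) in siILF2. NDUFA13 lay at 4.41 ± 0.124 CPM in siILF2 and 14.7 ± 0.791 in siILF3 (SE 0.0901, adjusted p = 8.2e-14), and plastin gene PLS3 at 219.0 ± 0.667 and 595.6 ± 10.3 CPM (SE 0.0788, adjusted p = 2.32e-13). ZFR was higher in siILF2 (0.61), STRBP and ZFR2 did not pass, and MYC was lower, at 53.7 ± 2.03 against 119.1 ± 3.3 CPM (−1.15).

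In ribosome biogenesis 23 fell, 0 rose and 15 did not pass (28 and 0 adjusted over the list alone) in siILF2 relative to siILF3 (camera's adjusted p = 8.26e-12). In ribosomal proteins 38 fell, 0 rose and 41 did not pass (50 and 0 adjusted over the list alone) (adjusted p = 3.33e-11). Oxidative phosphorylation had 20 falls, 0 rises and 15 not passed (21 and 0 adjusted over the list alone) (adjusted p = 1.78e-08), led by SDHB (−0.54) and NDUFB10 (−0.52). For G2/M mitosis genes 18 fell, 0 rose and 14 did not pass (20 and 0 adjusted over the list alone) (adjusted p = 2.12e-07), with PTTG1 (−0.60) and UBE2C (−0.47), and for ATF4 targets 15 fell, 0 rose and 11 did not pass (18 and 1 adjusted over the list alone) (adjusted p = 5.23e-08), with MTHFD2 (−1.01) and SLC7A5 (−1.03). In the core spliceosome 16 fell, 0 rose and 34 did not pass (17 and 0 adjusted over the list alone) (adjusted p = 1.15e-05), led by SNRPC (−1.004) and SNRPE (−0.53). Genes with a mean of at least 5 CPM and no siNS heptamer also leaned lower in siILF2: 12.2% were higher and 27.4% lower, with a median of −0.0609. The median of all tested genes was 0.021. Lists lower in siILF2 were not set against matched genes in this comparison, so part of their fall may be shared with other well-expressed genes. Interferon-stimulated genes had 14 rises, 3 falls and 22 not passed (16 and 4 adjusted over the list alone) (adjusted p = 0.00588), with SAMD9 (0.92) and LGALS3BP (−0.56). Nuclear-retained long noncoding RNAs had 3 rises, 0 falls and 2 not passed (4 and 0 adjusted over the list alone) (adjusted p = 0.0051), with NEAT1 (0.75) and TUG1 (0.42). Fibroblast and mesenchymal markers had 5 rises, 0 falls and 7 not passed (5 and 2 adjusted over the list alone) (adjusted p = 0.0231), a call lost without genes that carry the siNS heptamer (adjusted p = 0.0794). Nonsense-mediated decay factors had 6 falls, 0 rises and 11 not passed (7 and 0 adjusted over the list alone) (adjusted p = 0.0402), lost without siILF2 replicate 3 (0.105), siILF3 replicate 2 (0.0597) or genes with the siNS heptamer (0.0673). Endothelial markers, all under 2 CPM, had 2 rises, 0 falls and 2 not passed (3 and 0 adjusted over the list alone) (adjusted p = 0.0402), lost without siILF3 replicate 3 (0.0569).

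The comparison of siZFR with siILF2 asks where the effects of ZFR and ILF2 loss part. Targets of p53, endoplasmic reticulum chaperones, antigen presentation genes and neuronal markers were higher in siZFR, and ribosomal proteins, histones, G1/S replication genes, nonsense-mediated decay substrates and splicing proteins were lower. Its 15 list calls were lost with an estimated correlation (adjusted p from 0.117 to 0.915). The test called 7185 of 23869 genes, 3699 higher and 3486 lower in siZFR, with 594 and 345 at least 2-fold. ZFR differed by −3.34 (SE 0.073, adjusted p = 5.22e-23), ILF2 by 1.86 and MACROH2A1 by −1.81 (SE 0.0665, adjusted p = 3e-17). Further large differences were BEX1 (1.81), INPP5D (1.76), SCAMP5 (1.75) and APH1B (1.53) and KPNA6 (−1.60), CASP7 (−1.36) and CREBL2 (−1.30). ILF3 was lower in siZFR (−0.52). STRBP was also lower (−0.19, adjusted p = 0.0333), a call lost without siZFR replicates 1 or 2 (0.102, 0.111) or siILF2 replicates 1, 2 or 3 (0.0639, 0.0618, 0.128).

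For p53 targets 19 rose, 1 fell and 5 did not pass (20 and 1 adjusted over the list alone) in siZFR relative to siILF2 (camera's adjusted p = 3.32e-13, or 0.117 with an estimated correlation), led by CDKN1A (0.95), SPATA18 (1.09) and GDF15 (1.76). Endoplasmic reticulum chaperones had 11 rises, 0 falls and 9 not passed (14 and 0 adjusted over the list alone) (adjusted p = 5.16e-05), with EDEM1 (0.98) and HSPA5 (0.63). Neuronal markers had 7 rises, 1 fall and 6 not passed (8 and 2 adjusted over the list alone) (adjusted p = 0.00214, or 0.117 with an estimated correlation), with SYP (1.52) and INA (1.10). Antigen presentation genes had 7 rises, 2 falls and 6 not passed (7 and 2 adjusted over the list alone) (adjusted p = 0.0283), lost without siZFR replicate 1 (0.0559). Epithelial markers had 4 rises, 0 falls and 3 not passed (4 and 0 adjusted over the list alone) (adjusted p = 0.0433), lost without siZFR replicates 1 or 3 (0.0724, 0.0577) or siILF2 replicate 1 (0.0926). Ribosomal proteins had 53 falls, 0 rises and 26 not passed (58 and 0 adjusted over the list alone) (adjusted p = 8.5e-13). Histones had 9 falls, 0 rises and 7 not passed (9 and 0 adjusted over the list alone) (adjusted p = 5.16e-05). G1/S replication genes had 20 falls, 4 rises and 7 not passed (23 and 4 adjusted over the list alone) (adjusted p = 1.75e-05). Replication factor RPA2 (1.36) was higher in siZFR. It fell in siILF2 against siNS and did not pass in siZFR (adjusted p = 0.49) or siILF3 (adjusted p = 0.113). Nonsense-mediated decay substrates had 11 falls, 1 rise and 4 not passed (11 and 2 adjusted over the list alone) (adjusted p = 5.41e-05), with GAS5 (−0.68) and SNHG1 (−0.65). Homologous recombination and Fanconi genes had 10 falls, 2 rises and 19 not passed (10 and 2 adjusted over the list alone) (adjusted p = 0.0186).

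SR proteins were lower in siZFR than in siILF2: 8 fell, 1 rose and 4 did not pass (8 and 1 adjusted over the list alone) (adjusted p = 0.00456), with SRSF5 (−0.64), SRSF2 (−0.50) and SRSF7 (−0.38). Ribosome biogenesis had 13 falls, 1 rise and 24 not passed (14 and 1 adjusted over the list alone) (adjusted p = 0.0146), lost without siZFR replicate 2 (0.096) and with fry (0.0761). The hnRNP proteins had 12 falls, 3 rises and 12 not passed (12 and 4 adjusted over the list alone) (adjusted p = 0.0219), lost without siZFR replicate 1 (0.117) or siILF2 replicate 1 (0.0595). In the core spliceosome 14 fell, 4 rose and 32 did not pass (15 and 4 adjusted over the list alone) (adjusted p = 0.0426), lost without siZFR replicate 2 (0.259) or siILF2 replicate 2 (0.132) and with fry (0.191). Other splicing regulators had 13 falls, 5 rises and 16 not passed (14 and 5 adjusted over the list alone) (adjusted p = 0.0433), lost without siZFR replicates 1 or 3 (0.193, 0.057) or siILF2 replicate 1 (0.11).

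The comparison of siZFR with siILF3 asks where the effects of ZFR and ILF3 loss part, and more genes differed here than in any of the other 5 comparisons. Against siNS, ZFR RNA fell 4.11-fold in siZFR and ILF3 RNA 2.02-fold in siILF3, so unequal depth of knockdown may enter these differences too. Every measured ribosomal protein gene was lower in siZFR, with a median of −0.457. The median was −0.297 (range −0.355 to −0.21) in 1000 matched sets of other genes. Matching was on expression and on the length and GC content of the longest annotated transcript. Ribosome biogenesis, oxidative phosphorylation, mitosis, core spliceosome, hnRNP and SR protein lists were lower as well, while p53 targets, neuronal markers and nuclear-retained long noncoding RNAs were higher. Medians were −0.366 for ribosome biogenesis, against −0.152 in matched sets (−0.307 to 0.0162), and −0.252 for oxidative phosphorylation, against −0.185 (−0.335 to 0.00728). No other list or comparison was set against matched genes. No list of the 16 called here held with an estimated correlation (adjusted p from 0.0653 to 0.463). The test called 8711 of 23869 genes, 4238 higher and 4473 lower in siZFR, with 974 and 223 at least 2-fold. INPP5D differed most among the higher genes, at 13.7 ± 0.816 against 2.26 ± 0.329 CPM (2.60, SE 0.107, adjusted p = 2.86e-16), followed by SCAMP5 (1.98), APOE (1.82), SLC22A17 (1.80) and SSPOP (1.73). Lower in siZFR were ZFR (−2.73, SE 0.0712, adjusted p = 6.02e-21), MACROH2A1 (−2.44, SE 0.0678, adjusted p = 1.67e-20), MYC at 29.6 ± 2.62 against 119.1 ± 3.3 CPM (−2.01, SE 0.0718, adjusted p = 9.15e-18), KPNA6 (−1.47) and CA2 (−1.45). ILF3 was higher in siZFR (1.15) and STRBP lower (−0.23). ILF2 was lower (−0.25, adjusted p = 0.0082), a call lost without siZFR replicate 2 (0.0537).

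Ribosomal protein genes had 79 falls, 0 rises and 0 not passed (79 and 0 adjusted over the list alone) in siZFR relative to siILF3 (camera's adjusted p = 1.31e-29, or 0.332 with an estimated correlation), with RPS10 (−0.99), RPS6 (−0.70) and RPL22 (−0.57) in front. Ribosome biogenesis had 32 falls, 0 rises and 6 not passed (33 and 0 adjusted over the list alone) (adjusted p = 5.36e-15, or 0.224 with an estimated correlation), led by GNL3 (−0.76), NOP14 (−0.65) and PNO1 (−0.63). Oxidative phosphorylation had 26 falls, 0 rises and 9 not passed (28 and 0 adjusted over the list alone) (adjusted p = 1.88e-08, or 0.357 with an estimated correlation). For p53 targets 21 rose, 1 fell and 3 did not pass (22 and 1 adjusted over the list alone) (adjusted p = 6.65e-14, or 0.112 with an estimated correlation), with CDKN1A (1.39), TP53I3 (1.59) and SPATA18 (1.07). G2/M mitosis genes had 21 falls, 2 rises and 9 not passed (24 and 2 adjusted over the list alone) (adjusted p = 2.88e-08). G1/S replication genes had 17 falls, 3 rises and 11 not passed (20 and 3 adjusted over the list alone) (adjusted p = 1.49e-05). Histones had 12 falls, 1 rise and 3 not passed (13 and 1 adjusted over the list alone) (adjusted p = 1.26e-05). ATF4 targets had 18 falls, 1 rise and 7 not passed (18 and 3 adjusted over the list alone) (adjusted p = 9.94e-06). Nonsense-mediated decay substrates had 12 falls, 1 rise and 3 not passed (13 and 1 adjusted over the list alone) (adjusted p = 6.63e-07), with GAS5 (−0.80) and SNHG8 (−0.78). Neuronal markers had 8 rises, 0 falls and 6 not passed (9 and 0 adjusted over the list alone) (adjusted p = 4.05e-05, or 0.0653 with an estimated correlation), among them INA (0.95), SYT1 (0.86) and MAP2 (0.86). All nuclear-retained long noncoding RNAs of the list were higher (5 rose, 0 fell and 0 did not pass (5 and 0 adjusted over the list alone), adjusted p = 0.00688), with NEAT1 (0.73) and TUG1 (0.37), although KCNQ1OT1 lost its call without siZFR replicate 2 (0.3) or siILF3 replicate 2 (0.0537).

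Of the splicing lists, the core spliceosome, hnRNP proteins and SR proteins were lower in siZFR than in siILF3. The core spliceosome had 29 falls, 0 rises and 21 not passed (32 and 0 adjusted over the list alone) (adjusted p = 7.01e-09), with SNRPA (−0.76), SNRNP70 (−0.55) and SNRNP40 (−0.53) in front. For hnRNP proteins 14 fell, 1 rose and 12 did not pass (15 and 2 adjusted over the list alone) (adjusted p = 0.000327), led by HNRNPDL (−0.81), HNRNPLL (−0.49) and HNRNPA1 (−0.56), and for SR proteins 8 fell, 2 rose and 3 did not pass (8 and 2 adjusted over the list alone) (adjusted p = 0.00785), led by SRSF7 (−0.56) and SRSF2 (−0.54). Other splicing regulators had 13 falls, 6 rises and 15 not passed (14 and 7 adjusted over the list alone) and did not pass (adjusted p = 0.103), except without siZFR replicate 2 (0.00962). Endoplasmic reticulum chaperones had 8 rises, 2 falls and 10 not passed (8 and 2 adjusted over the list alone) (adjusted p = 0.026), with DNAJB9 (1.12) and EDEM1 (0.75), a call lost without siZFR replicate 1 (0.0642) or siILF3 replicate 3 (0.0689). Homologous recombination and Fanconi genes had 13 falls, 3 rises and 15 not passed (13 and 3 adjusted over the list alone) (adjusted p = 0.0246), lost without siZFR replicate 1 (0.0509) or siILF3 replicate 3 (0.0594).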

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

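The differences between knockdowns below were planned comparisons, the test of ribosomal proteins against matched genes was written before its result was seen, the same test of the other 2 lists was added after that result, with predictions written before its own, and the recount of p53 targets without genes that carry GCAGTAC or CAGTACA in the 3′ UTR was chosen after the data were seen. Lists were singled out where they passed in opposite directions in 2 knockdowns against siNS and the direct comparison of those knockdowns passed too. That comparison is the difference of the 2 against siNS in the same fit. Its adjusted p values below were part of the selection and are no separate support.

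Targets of p53 had a median log2 fold change of 0.195 in siZFR, −0.214 in siILF2 and −0.25 in siILF3. The median difference was 0.458 between siZFR and siILF2, with 19 of 25 genes higher and 1 lower (camera's adjusted p = 3.32e-13, adjusted p = 0.117 with an estimated correlation). Between siZFR and siILF3 it was 0.437, with 21 higher and 1 lower (adjusted p = 6.65e-14, adjusted p = 0.112 with an estimated correlation). Of the 25 genes 7 carry GCAGTAC or CAGTACA. Without them the rise in siZFR against siNS did not pass (adjusted p = 0.196), as the median fell from 0.195 (quartiles 0.00679 and 0.277) to 0.105 (−0.0253 and 0.224) and 18 genes were left. The medians of those 18 were −0.297 in siILF2 and −0.339 in siILF3 against siNS, and 0.489 between siZFR and siILF2 and 0.415 between siZFR and siILF3. The opposite direction in siZFR against siNS thus rests in part on carriers of these heptamers, and the differences between knockdowns do not. No other technical explanation was tested for this list.

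Cytosolic ribosomal proteins had medians of −0.209 in siZFR and 0.265 in siILF3, and a median difference of −0.457 with all 79 genes lower in siZFR (adjusted p = 1.31e-29, adjusted p = 0.332 with an estimated correlation). For ribosome biogenesis the difference was −0.366, with 32 of 38 genes lower (adjusted p = 5.36e-15, adjusted p = 0.224 with an estimated correlation). Nuclear-encoded oxidative phosphorylation differed by −0.252, with 26 of 35 genes lower (adjusted p = 1.88e-08, adjusted p = 0.357 with an estimated correlation).

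A bias by transcript length, GC content or expression was weighed for these 3 lists. Length and GC content were those of the longest annotated transcript of each gene. Its median length was 1857 bases for ribosomal proteins and 2006 in the matched sets. The RNA expressed may be shorter, so a bias by its length was not tested for any of these lists. In 1000 sets of other genes matched to the ribosomal proteins, the median difference was −0.297 (range −0.355 to −0.21), so genes alike in these respects were lower in siZFR too, by less than the −0.457 of the ribosomal proteins. The matched sets had a mean log2 CPM of 8.02 against 8.67 for the ribosomal proteins, so abundance may account for part of the difference beyond that of the sets. The difference is taken between siZFR and siILF3, so siNS levels do not enter it. Reads from pseudogenes and a change in growth after knockdown remain open and were not tested.

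For ribosome biogenesis the matched sets had a median difference of −0.152 (range −0.307 to 0.0162), which the −0.366 of the list exceeds. The properties as matched thus account for less than the whole, while a bias by the length of the expressed RNA stays open. For oxidative phosphorylation it was −0.185 (−0.335 to 0.00728), and the −0.252 of the list lies inside that range. The difference of oxidative phosphorylation may thus come from transcript length, GC content or expression alone, and it is not taken as an effect on that pathway.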

How the results depend on the processing

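All alternatives were planned except the recount without genes that carry the siNS heptamer (GCAGTAC or CAGTACA) in the 3′ UTR, the splits of siNS libraries between knockdowns and the recount of decay substrates without members of the ATF4 list, which were chosen after the data were seen. Under 7 alternatives (DESeq2 size factors, no low-count filter, a mean of at least 5 CPM, the DESeq2 Wald test, limma-voom, a fit of the 6 libraries compared, a replicate block) and with each of the libraries compared left out in turn, every count of changed, raised or lowered genes stayed within 1.5 times its value. With DESeq2 size factors 6128 of 6306, 6620 of 6716 and 7355 of 7499 called genes were shared for siZFR, siILF2 and siILF3 against siNS, and the median log2 fold change of all genes moved by at most 0.012. A similar count does not mean the same genes. With a mean of at least 5 CPM, 5243, 5390 and 5392 genes were called in these comparisons. Of those, 4400, 4678 and 4364 were also called in the main fit. With each of the 6 libraries compared left out in turn the counts ran from 5200 to 6161 for siZFR, 5342 to 6817 for siILF2 and 6009 to 7046 for siILF3 against siNS, from 4462 to 5287 for siILF2 against siILF3, 5564 to 6879 for siZFR against siILF2 and 7092 to 8619 for siZFR against siILF3. Without siNS replicate 3, which enters the last 3 comparisons only through the shared scaling, filter and dispersion, these counts were 6791, 7824 and 9354. Where a group is left with 2 libraries, its spread is taken from all groups. Of 731 called values of named genes 675 kept their call with each of the 6 libraries compared left out in turn and 56 lost it at least once, and of 75 called lists 61 kept it and 14 lost it. No direction reversed.

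Correlations of fold changes moved. With a mean of at least 5 CPM they were 0.541 (siZFR and siILF2), 0.461 (siZFR and siILF3) and 0.645 (siILF2 and siILF3), where the sparsest genes are left out by construction. With each library left out they ran from 0.382 to 0.502, from 0.341 to 0.441 and from 0.547 to 0.641, and the cause was not tested. With siNS libraries split so that none served 2 knockdowns, median correlations were 0.1695, 0.131 and 0.2955, where no control noise is shared. The numbers of genes raised in both fell to 708.5, 727 and 978, those lowered in both to 711, 630.5 and 1106, and those raised and lowered in all 3 to 436.5 and 285, where fewer control libraries enter each test. Without genes that carry the siNS heptamer, 615 genes rose in all 3 knockdowns in place of 932, where fewer genes are counted, and 768 fell in place of 808. The 75 list calls were all lost with an estimated correlation, and fry lost 4 of them and added 33. Those lost with fry were histones and oxidative phosphorylation in siZFR against siNS, and the core spliceosome and ribosome biogenesis in siZFR against siILF2. Without genes that carry the siNS heptamer 4 list calls were lost and 6 gained. Decay substrates without members of the ATF4 list lost their call in siILF3 (adjusted p = 0.239) and kept it in the 4 other comparisons with a call. Mitochondrially encoded mRNAs passed without siNS replicate 3 in all 3 knockdowns (adjusted p = 0.0408, 0.00481 and 0.0383).

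Replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at −0.585 to 0.328, 6 of 18 pairs exceeded 0.1, and 4 of 12 libraries correlated best with their own number. With the replicate number as a block the counts of changed genes were 6110, 6571 and 7352 for siZFR, siILF2 and siILF3 against siNS, 5834 for siILF2 against siILF3, 7017 for siZFR against siILF2 and 8533 for siZFR against siILF3. Under the block 2 called values of named genes were lost and 2 gained, and 1 list was gained, ATF4 and integrated stress response in siILF3 (adjusted p = 0.0241).

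In fits of the 6 libraries compared, 1 of the 10 possible splits into 3 and 3, the real one, gave as many genes in each comparison, and 10 splits are too few for a share under 0.05. The real splits gave 5154, 7042 and 7714 genes for siZFR, siILF2 and siILF3 against siNS, and the highest of the other splits gave 0, 1 and 0. For siILF2 against siILF3, siZFR against siILF2 and siZFR against siILF3 the real splits gave 7886, 7050 and 8536 and the highest others 1, 1 and 0.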

Other observations

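Lists not described with the comparisons come first. The tests of heptamers were chosen after the data were seen. The hexamer is the core of GCAGTAC, and the prediction for genes without it was written before its own result. As a list, the 5 DZF family genes did not pass. In siZFR 2 fell, 0 rose and 3 did not pass (2 and 0 adjusted over the list alone) (camera adjusted p = 0.0861, or 0.572 with an estimated correlation). Cholesterol synthesis genes passed in none of the 3 knockdowns against siNS with all libraries and genes. The siILF2 list passed without siNS replicate 3 (adjusted p = 0.0177), siILF2 replicate 2 (0.0466) or genes that carry the siNS heptamer (0.0417). In siILF2 7 fell, 2 rose and 16 did not pass (7 and 2 adjusted over the list alone) (camera adjusted p = 0.0756, or 0.808 with an estimated correlation), led by LSS (−0.81), INSIG1 (−0.51) and MSMO1 (0.53). In siILF3 8 rose, 4 fell and 13 did not pass (9 and 4 adjusted over the list alone) (camera adjusted p = 0.683, or 0.894 with an estimated correlation). In siZFR 6 fell, 4 rose and 15 did not pass (7 and 4 adjusted over the list alone) (camera adjusted p = 0.795, or 0.988 with an estimated correlation).

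Immediate early genes did not pass either. In siZFR 2 rose, 2 fell and 14 did not pass (2 and 2 adjusted over the list alone) (camera adjusted p = 0.978, or 0.988 with an estimated correlation). In siILF2 4 rose, 4 fell and 10 did not pass (6 and 4 adjusted over the list alone) (camera adjusted p = 0.913, or 0.951 with an estimated correlation). In siILF3 4 rose, 3 fell and 11 did not pass (6 and 3 adjusted over the list alone) (camera adjusted p = 0.332, or 0.636 with an estimated correlation). Of these, MYC fell in siZFR (−0.67) and rose in siILF3 (1.34). Its rise in siILF2 (0.19, adjusted p = 0.0425) was lost in 5 of 6 fits with 1 library compared left out (adjusted p from 0.0667 to 0.173), among them that without siNS replicate 3 (0.13, adjusted p = 0.161). ARC rose in siILF3 from 1.58 ± 0.318 to 3.69 ± 0.436 CPM (SD, n = 3). Of NF-kB and inflammatory targets in siZFR 2 rose, 2 fell and 12 did not pass (2 and 2 adjusted over the list alone) (camera adjusted p = 0.935, or 0.988 with an estimated correlation). For siILF2, 2 fell, 1 rose and 13 did not pass (2 and 1 adjusted over the list alone) (camera adjusted p = 0.916, or 0.951 with an estimated correlation). For siILF3 2 fell, 1 rose and 13 did not pass (2 and 0 adjusted over the list alone) (camera adjusted p = 0.118, or 0.415 with an estimated correlation). IER3 rose in siZFR (0.62) and siILF2 (0.70).

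Of mitochondrially encoded mRNAs in siZFR 1 rose, 0 fell and 12 did not pass (0 and 0 adjusted over the list alone) (camera adjusted p = 0.939, or 0.988 with an estimated correlation). In siILF2 0 rose, 0 fell and 13 did not pass (0 and 0 adjusted over the list alone) (camera adjusted p = 0.483, or 0.951 with an estimated correlation). In siILF3 1 rose, 1 fell and 11 did not pass (1 and 1 adjusted over the list alone) (camera adjusted p = 0.998, or 0.999 with an estimated correlation). Of blood cell markers in siZFR 0 rose, 0 fell and 5 did not pass (0 and 0 adjusted over the list alone) (camera adjusted p = 0.896, or 0.988 with an estimated correlation). For siILF2, 1 rose, 1 fell and 3 did not pass (1 and 2 adjusted over the list alone) (camera adjusted p = 0.896, or 0.951 with an estimated correlation). For siILF3 0 rose, 0 fell and 5 did not pass (0 and 0 adjusted over the list alone) (camera adjusted p = 0.848, or 0.88 with an estimated correlation). The list of recombination and Fanconi genes did not pass against siNS (camera adjusted p = 0.443, 0.155 and 0.118 in siZFR, siILF2 and siILF3).

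Genes that rose in all 3 knockdowns may in part be genes that the non-silencing siRNA itself lowers through its seed. The heptamer GCAGTAC, picked among all 16384 in a first set of genes, raised the mean change against siNS by 0.2631 (SE 0.0144) in 5284 other genes (permutation p = 0.0001, the smallest that 10000 permutations can give), against 0.1132 (SE 0.00896) for the same heptamer elsewhere in the transcript. The next values are means with UTR length, GC content and expression taken out. Genes with the octamer GCAGTACA stood at 0.31 and those with the heptamer alone at 0.20. Those with CAGTACA alone, 420 genes also counted as carriers, stood at 0.0112 (SE 0.0108). Genes with the hexamer CAGTAC alone stood at −0.00566 (SE 0.00939) and those without it in the 3′ UTR at −0.0195 (SE 0.00349). Slopes in the comparisons without siNS, with terms for UTR length, GC content and expression, were 0.0106 (SE 0.0102), −0.0101 (SE 0.0122) and −0.000211 (SE 0.0121). Of genes raised in all 3 knockdowns with a 3′ UTR to search, 37.1% carry GCAGTAC or CAGTACA there and 23.8% hold no hexamer anywhere in the longest transcript. Without the hexamer were also 51.1% of all searched genes and 54% of those lowered in all 3, with no adjustment for transcript length. The share of 23.8% decides nothing, as the hexamer alone came with no clear rise. The siRNA sequences are not given, and for all of these genes, with or without the heptamer, a shared loss of DZF protein function and an endogenous small RNA with this seed stay open.

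Each knockdown may also carry its own seed effect. The heptamer GAAGTGC shifted changes in siILF2 relative to the other 2 knockdowns by −0.1082 (SE 0.0103, permutation p = 0.0001) and occurs in 4 of 5 annotated ILF2 transcripts, against 12.7% of genes of similar length, while the heptamers of the other siRNAs occur in 0 of 5. For siILF3, ACGAAAT gave −0.1156 (SE 0.0207, permutation p = 0.0001) and occurs in 14 of 24 ILF3 transcripts, against 8.12% of genes of similar length. ILF3 transcripts also hold the heptamers of siNS (11 of 24), siILF2 (9) and siZFR (8), so this presence is weak support. For siZFR the heptamer GGAGTGC gave −0.0261 (SE 0.0104, permutation p = 0.0114), while all genes together picked another, GGCGAAG, found in 1 of 7 ZFR transcripts, so its case stays open, and no second siRNA per gene separates a seed effect from loss of the targeted protein.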
